A study of Mus musculus with 90 samples.

How the data were processed

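The series holds 90 one-colour Affymetrix Mouse 430 2.0 arrays, 1 array per sample and tissue. They form 18 groups of 5 arrays (2 tissues, time 0, and 3, 6, 9 and 12 h of sleep or of deprivation). Whether the 2 tissues came from the same mice is not known. Total RNA (5 ug) was amplified and biotin-labelled by the submitters. The deposited values are intensity, as linear MAS5 probe set signals; the labels name MAS5 without a version. On each array the submitters had scaled them so that the mean without the lowest and highest 2% of probe sets is close to 150, and no further normalization between arrays was seen in the values. The table holds 45101 probe sets, of which 64 controls were used only for checks. The depth of such a table is the number of arrays, so precision is limited by 5 arrays a group. The standard errors of the tests combine that number with a spread estimated from all arrays of the fit. This holds also for comparisons at a single time, except where fits of only the 2 groups compared are named.

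Values were taken as log2(value + 16), and 120 values in the whole table are 0. Fold changes in the text are of signal plus 16, so the added 16 pulls them towards no change. In each tissue, probe sets with a mean above the median of all were kept (percentile 50), that is 22518 with a mean log2 above 6.14 in cortex (signal 54.3) and 6.19 in hypothalamus (signal 57.1). Of these 21450 passed in both tissues and were used for the comparison between tissues. Probe sets were named from the platform annotation when they gave 1 gene: 34958 did, 932 gave several and 9147 none, for 18194 distinct genes. A second gene table matched 34754 of those names by Entrez number, left 204 unmatched and changed none.

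Tests used limma 3.58.1 in R 4.3.3, with 1 mean for each group, empirical Bayes with an intensity trend, 2-sided p-values and Benjamini-Hochberg adjustment at 0.05 over all probe sets of a tissue. The comparisons in each tissue were deprived minus sleeping as a mean of the 4 times and at each time, linear trends from time 0 over the hours of sleep and over the hours of deprivation, and the growth of the difference between deprived and sleeping mice per hour. The last comparison was the difference between the tissues in the mean effect, from 1 fit over all 90 arrays. Sleep and deprivation trends share the time 0 arrays, so their overlap was not counted. A call means an adjusted p under 0.05, and the text says rose or fell only for calls. The expected number of shared calls between tissues is the product of the 2 counts over 21450. It takes the tissues as independent, although they may come from the same mice.

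Gene lists were tested with camera of limma at a preset correlation of 0.01 between genes and again with the correlation estimated from the data, adjusted over 31 lists. Each gene of a list was represented by its probe set with the highest mean. A total of 33 lists of functions and cell markers were fixed, and the 2 with fewer than 5 measured genes (red blood cell and pituitary, 2 genes each) were only described. The number adjusted over the list alone uses the p-values of the list's own genes. The comparisons, lists, rules for naming genes and most alternatives were fixed before the data were examined. Genes named are the 10 largest rises and 10 largest falls of the mean comparison with 1 sign at all 4 times, the 3 largest each way at single times, the 5 steepest each way for trends and growth, the 5 largest each way for the tissue difference, up to 4 genes of a list with the smallest adjusted p, and 8 further genes chosen in advance. Rbm3 was also chosen in advance, but no probe set that names it alone passed the filter in either tissue. A gene with several probe sets has the one that ranked, and other probe sets with the opposite sign are stated where the text names them.

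The labelling series were read from ranges of the title numbers and from the poly-A control probe sets after the values had been examined, and entered the fit as an additive block. Comparisons within 1 series used the times that have both states in it. Further alternatives were no filter, a filter at percentile 70, quantile normalization, log2(value + 1), the replicate number of the labels as a block, each array left out in turn, only the 2 groups compared, a block for late against early hours, the mean over all probe sets of a gene in list tests, and arrays whose title numbers differ by 79 as 1 animal. Chosen after the data were seen were the series block, the Gapdh 3' to 5' ratio as a covariate, the scores of 4 marker lists as covariates and leaving out 2 doubted cortex arrays. The groups were also re-divided at random 100 times for each comparison, the real division included. Array measures were compared between states by permutation (1e+05 resamples, so 1e-05 is the smallest p), and with 5 against 5 arrays the smallest exact p is 0.0079.

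No 2 arrays were identical, and the highest correlation between any 2 was 0.982. The procedure was tested on simulated data with the real variance: of probe sets changed by 0.3 or 0.6 on the log2 scale, 65% and 96% were found in the cortical mean comparison, 62% and 95% in the hypothalamic one, and 2% and 43% at 6 h in hypothalamus. Of 171 calls in the simulated cortical mean comparison 10 were false. Of 30 simulated lists of 20 genes in cortex, the 1 shifted by 0.15 had a camera adjusted p of 3.22e-13, and none of the others was called. The simulated genes varied independently, so this gives no assurance for real lists, whose genes can vary together. Probe sets that name several genes or none were counted but not named. Some genes were not analysed here.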

Results

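Gene expression was measured on 90 one-colour Affymetrix arrays, 45 from the motor areas of the cerebral cortex and 45 from the hypothalamus of male C57BL/6J mice aged 10 weeks. Mice had food only in the dark phase and were adapted for 14 days. In each tissue, 5 mice were killed at lights-on (time 0, 7 AM). Further groups of 5 were killed after 3, 6, 9 or 12 h of undisturbed sleep, or after as many hours of sleep deprivation by gentle handling from lights-on. Every array had a deposited signal for each probe set, scaled so that the trimmed mean lay between 149.9 and 150.4. The median signal was 56.8 ± 3.61 (SD) in cortex and 58.8 ± 3.22 in hypothalamus. Probe sets above the median of their tissue were tested, 22518 in each, and these covered 11212 named genes in cortex and 11386 in hypothalamus. Marker genes of the cortex had a mean log2 signal of at least 9.15 in every cortex array and at most 8.353 in every hypothalamus array, so no array looked swapped between tissues.

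The labels name no batch. Ranges of the title numbers split the arrays into what is here called labelling series, which were found after the values had been seen. The cortex has 2 series, of 26 and 19 arrays. The hypothalamus has 5, of 2, 5, 22, 10 and 6 arrays, and its series of 6 arrays had poly-A control probe sets at a mean log2 of 9.94 against 6.65 to 7.15 in the others. These controls did not separate the 2 cortical series (7.151 to 9.122 and 6.912 to 7.979). They also overlapped between the hypothalamic series of 22 and of 10 (6.446 to 7.137 and 6.963 to 7.337). Whether arrays of different series were labelled apart is therefore not known. At 6 h in the hypothalamus 3 of the 5 deprived arrays and none of the sleeping ones belong to the series of 22, while 4 of the 5 sleeping arrays belong to the series of 10. In cortex the groups of 6, 9 and 12 h each lie within 1 series, but at 3 h the sleeping arrays lie in 1 series and the deprived arrays in both. Counts of calls are therefore given also with the series as an additive block (called blocked), as are calls of named genes or lists that the block took away. Genes and lists called only when blocked are not all named. A call lost when blocked can reflect a larger standard error as well as a smaller difference.

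The first question was which cortical genes differed between deprived and sleeping mice of the same clock hour, averaged over the 4 times (20 arrays against 20). Homer1, a scaffold gene of the postsynapse, rose most, by 1.57 ± 0.0964 (SE) on the log2 scale, or 2.97-fold, at the probe set that ranked (adjusted p 1.53e-15). In all 20 deprived arrays this probe set lay above every sleeping array of its time. Of the 4 other Homer1 probe sets 3 rose too. The one with the highest mean signal rose by only 0.291, or 1.22-fold (adjusted p 0.00152), so the size of the rise depends on the probe set. The stress peptide gene Crh rose by 0.95 (adjusted p 8.22e-12) and Dio2, which activates thyroid hormone, by 0.79 (adjusted p 1.61e-13). The activity-regulated genes Arc, Fosl2, Egr2 and Inhba rose by 1.11, 0.83, 0.77 and 0.77. The chaperone genes Hspb1, Hspa5 and Hspa1b rose by 0.85, 0.76 and 0.75. Fos, the best known of the immediate early genes, rose by 0.61 (adjusted p 0.00512).

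Among the cortical genes that fell, the cold-inducible RNA-binding protein gene Cirbp changed most, by -1.03 ± 0.11 (adjusted p 6.04e-09), and 19 of 20 deprived arrays lay below every sleeping array of their time. Opalin, a gene of mature oligodendrocytes, fell by 0.68 (adjusted p 6.43e-11), and the clock output gene Dbp fell by 0.64 (adjusted p 3.57e-09). Cc2d1b, Krt12, Haghl, Fads3, Hnrnpdl, Reep6 and Sbsn made up the other 7 of the 10 largest falls with 1 sign at all 4 times, at -0.69, -0.64, -0.62, -0.54, -0.52, -0.52 and -0.52. Other probe sets disagreed in sign for Cc2d1b (its only other one) and Haghl (1 of 3). All 20 genes with the largest changes kept their calls when blocked, with Homer1 at 1.59, Cirbp at -0.89 and Opalin at -0.65. The block could change only the 3 h part of these means, since the other times lie within 1 series each. Within the series of 26 arrays (compared at 9 and 12 h) and of 19 (3 and 6 h), Homer1 changed by 1.78 and 1.36 and Crh by 1.13 and 0.82. Cirbp changed there by -0.94 and -0.83, and Opalin by -0.78 and -0.51. These pairs of values differ in hours as well as in series. In total 3051 of 22518 cortical probe sets were called (1590 higher, 1461 lower, 2314 genes), 2886 when blocked and 2446 in both fits, yet only 3 passed a 2-fold change and the median size was 0.22.

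The cortical gene lists showed which functions moved. Of 26 immediate early and activity-regulated genes 19 rose and 1 fell (20 and 1 when adjusted over the list alone), with a median of 0.47 and a camera adjusted p of 6.21e-23; Egr3 rose by 0.67, Ptgs2 by 0.72 and Vgf by 0.49. The gene that fell was Btg2, at -0.27, named after its values were seen and lost when blocked (adjusted p 0.0835). Of 22 endoplasmic reticulum chaperone and unfolded protein response genes 13 rose (15 over the list alone), among them Hspa5, Manf at 0.52, Hsp90b1 at 0.45 and Xbp1 at 0.38, with a median of 0.22. Of 20 cytosolic heat shock genes 12 rose (17 over the list alone), such as Chordc1 at 0.60 and Hsph1 at 0.39, with a median of 0.16. Of 18 glucocorticoid-induced genes 10 rose, also over the list alone, such as Cdkn1a at 0.71 and Tsc22d3 at 0.41, with a median of 0.21. Of 19 genes of cholesterol synthesis and uptake 10 fell (14 over the list alone), with Mvd at -0.43, Sqle at -0.33 and Hmgcs1 at -0.32, and the median was -0.19. These 5 lists also passed when the correlation between genes was estimated from the data (adjusted p 0.00254 for 4 of them and 0.00754 for the glucocorticoid list). Their blocked medians were 0.47, 0.22, 0.16, 0.23 and -0.23.

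A further 6 cortical lists were called only with the preset correlation when the series was not a block. The cold-inducible and splicing list moved in both directions, with 7 of 18 genes higher (9 over the list alone) and 3 lower (4), Tra2a at 0.55 and Hnrnph1 at 0.30 against Cirbp, a median of 0.12 and an adjusted p of 0.211 with the estimated correlation. Of 17 neuropeptide genes 5 rose, also over the list alone, including Crh, Nts at 0.42 and Vip at 0.39 (estimated adjusted p 0.0991; blocked 0.0387, which passes). Of 17 myelin genes 4 fell, Opalin, Aspa at -0.39, Mog at -0.23 and Tspan2 at -0.15, with a median of only -0.0187 (estimated adjusted p 0.622). Antioxidant enzymes (1 rose and 3 fell of 20, median -0.0834), the respiratory chain (7 of 72 fell, among them Ndufs3 at -0.22, median -0.0505) and aminoacyl-tRNA synthetases (1 rose and 3 fell of 19, among the latter Vars at -0.25, median -0.0681) tended lower, with estimated adjusted p of 0.211, 0.776 and 0.349. Blocked, the myelin and aminoacyl-tRNA synthetase lists lost the preset call as well (adjusted p 0.0865 and 0.0619). The respiratory median was -0.106 in the series of 26 cortical arrays (compared at 9 and 12 h) and 0.065 in the series of 19 (3 and 6 h). Series and hours cannot be told apart in these values. The circadian clock list was not called: 3 of 21 genes rose, among them Per2 at 0.55 and Bhlhe40 at 0.41, and 4 fell, among them Dbp and Ciart at -0.42, while its median of 0.0431 and its test direction differed in sign. Per1 was not called in either tissue (adjusted p 0.215 in cortex and 0.221 in hypothalamus).

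Cortical changes were then tested at each time (5 arrays against 5). At 3 h 172 probe sets were called (103 higher, 69 lower); Arc rose by 1.99, Hspa1b by 1.29 and Med18 by 1.15, and Cirbp, Ilf2 and Mgst3 fell by 1.13, 0.84 and 0.78. Blocked, the 3 h count was 71 with 37 in both fits, and Arc (adjusted p 0.209), Med18 (0.175), Cirbp (0.267), Ilf2 (0.525) and Mgst3 (0.66) lost their calls. Arc and Med18 kept most of their size, at 1.71 and 1.16, while Cirbp, Ilf2 and Mgst3 shrank to -0.57, -0.39 and -0.27. At 6 h 295 were called (177 higher, 118 lower), with Homer1 at 1.77, Crh at 1.13 and Hspa5 at 1.00, and with Becn1 at -1.46, Cirbp at -1.09 and Gm11110 at -1.02. At 9 h 873 were called (533 higher, 340 lower), led by Homer1 at 1.82, Crh at 1.08 and Inhba at 1.06, and by Becn1 at -1.24, Cirbp at -1.22 and Psmd4 at -1.22. At 12 h 64 were called (38 higher, 26 lower), with Homer1 at 1.74, Crh at 1.18 and Sgsm1 at 0.88, and with Pllp at -0.87, Irak1 at -0.84 and Opalin at -0.83. At 6, 9 and 12 h both states lie in 1 series, so the block could not change a difference and tests nothing there. It changed only the estimated spread, and the counts were then 365, 996 and 84, with every earlier call kept. For Becn1, 3 of 4 other probe sets had the opposite sign at 6 h and all 4 at 9 h. For Homer1 it was 1 of 4 at 6 h, and of these 4 probe sets 0, 1 and 0 were called at 6, 9 and 12 h. With 5 arrays a group, 73% of simulated changes of 0.6 were found in cortex at 6 h and 14% of changes of 0.3, so a gene not called at a single time is not a gene without change.

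The hours of undisturbed sleep and the clock hour ran together, so trends over 0 to 12 h are changes along both (25 arrays a trend). In sleeping cortex 1470 probe sets had a slope (595 up, 875 down). Dbp rose by 0.13 ± 0.00815 per hour (adjusted p 3.43e-15), the clock gene Ciart by 0.148, and Txnip, Cysrt1 and Sgk1 by 0.109, 0.0962 and 0.0955. Homer1 fell by 0.144 ± 0.0144 per hour (adjusted p 4.5e-09), with signals of 727 at time 0 and 268 after 9 h of sleep, and Hspb1 fell by 0.127, followed by Anp32a at -0.101, Mpeg1 at -0.0918 and Wdr53 at -0.0905. Blocked, 887 probe sets had a slope with 482 in both fits and 9 reversed sign; Txnip (adjusted p 0.323), Cysrt1 (0.276), Mpeg1 (0.248) and Wdr53 (0.53) lost the call, and the slope of Anp32a reversed to 0.0113 per hour and was not called. In deprived cortex 2256 probe sets had a slope (1126 up, 1130 down; 2221 blocked and 1409 in both). Plin4 rose by 0.162 ± 0.0187 per hour, Sgk1 by 0.112, Ciart and Txnip by 0.105 and Gm19439 by 0.101, while Ptov1, Sostdc1, Psmd4, Smo and Anp32a changed by -0.138, -0.123, -0.122, -0.112 and -0.104. Of these, Txnip and Anp32a lost the call when blocked (adjusted p 0.0855 and 0.45). Other probe sets disagreed in sign for Ptov1 and Psmd4 (1 of 2 each), for Smo (its only other one) and, in the sleep trend, for Anp32a (1 of 2).

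Of the lists, glucocorticoid-induced genes rose with the hours in both cortical trends: in sleep 9 of 18 rose (13 over the list alone, median 0.0358 per hour, estimated adjusted p 0.00381) and in deprivation 11 (16, median 0.0336, 0.000506). In sleep the clock list went up (7 of 21 rose and 4 fell, estimated adjusted p 0.0448). Blocked, its median was -0.00167 and the list was not called (adjusted p 0.0548). Heat shock genes went down in sleep (7 of 20 fell, 11 over the list alone, median -0.024) and so did cold-inducible and splicing genes (7 of 18 fell and 1 rose, median -0.0187), both with an estimated adjusted p of 0.0448. Blocked, these were 0.0679 and 0.181, and the calls were lost. Immediate early genes (7 of 26 fell, 13 over the list alone) and endoplasmic reticulum chaperones (5 of 22, 8 over the list alone) had medians of -0.0294 and -0.0202 per hour and passed only with the preset correlation (estimated adjusted p 0.0597 for both). In deprivation the neuropeptide list rose, 7 of 17 genes (9 over the list alone) with Crh at 0.0797, Adcyap1 at 0.0565 and Vip at 0.0419 per hour (blocked adjusted p 0.0832, lost) and an estimated adjusted p of 0.0248. Heat shock genes (8 of 20 fell) and myelin genes (4 of 17 fell) declined in deprivation only with the preset correlation (estimated adjusted p 0.369 and 0.411). The cortical gap between deprived and sleeping mice changed with the hours for 1 probe set, Irak1, at -0.145 ± 0.0246 per hour (adjusted p 0.0119; blocked -0.125, adjusted p 0.104), while 1986 probe sets had an unadjusted p below 0.05 in limma.

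In the hypothalamus the same mean comparison (20 arrays against 20) called 1250 probe sets (553 higher, 697 lower, 1050 genes), but only 578 when blocked (290 higher, 288 lower), with 397 in both fits. Hspa1b, a stress-induced chaperone gene, rose most, by 1.47 ± 0.122 or 2.76-fold (adjusted p 5.72e-11; blocked 1.36), and 18 of 20 deprived arrays lay above every sleeping array of their time. Homer1 rose by 1.39 ± 0.167 (adjusted p 4.22e-07; blocked 1.29), though neither of its 2 other probe sets was called. Hspb1 rose by 1.09, the orphan nuclear receptor gene Nr4a3 by 0.96, the lipid droplet gene Plin4 by 0.80 and Ccn2 by 0.78, and all 4 were kept when blocked (1.01, 1.09, 0.77 and 0.67). Hsd3b3, at 1.17, shrank to 0.64 when blocked, and Gm19439 went from 0.81 to 0.70. Egr3 at 0.84 and Tbca at 0.80 lost the call (blocked adjusted p 0.0955 and 0.458), but Egr3 kept its size, at 0.82, while Tbca shrank to 0.32. Cirbp fell by 1.01 ± 0.122 (adjusted p 4.85e-07; blocked -0.69, adjusted p 1.6e-06) and Opalin by 0.66 ± 0.0991 (adjusted p 2.87e-05; blocked -0.69). Soga1 and Hnrnpdl fell by 0.62 and 0.53 and were kept at -0.46 and -0.33. Iffo2, Ajm1, Clip4, Ddx55, Baalc and Tmem38a, at -0.67, -0.58, -0.54, -0.53, -0.53 and -0.50, lost their calls (blocked adjusted p 0.129, 0.256, 0.506, 0.263, 0.34 and 0.5). Their blocked differences were -0.49, -0.37, -0.22, -0.34, -0.24 and -0.17. Other probe sets had the opposite sign for Iffo2 (its only other one) and Clip4 (1 of 5). Fos rose by 0.67 (adjusted p 0.00232) and Dbp fell by 0.40 (adjusted p 0.00282), while Arc at 0.44 and Per2 at 0.15 were not called (adjusted p 0.123 and 0.0872). Blocked, Per2 was called, at 0.20 (adjusted p 0.0328). The tissue difference had an adjusted p of 0.367 for Arc and 0.0489 for Per2 (blocked 0.603 and 0.272).

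Within the single hypothalamic series the arrays were few. The series of 22 had 6 deprived against 7 sleeping arrays at 9 and 12 h. In it 25 probe sets were called, among them Homer1 at 1.55, Plin4 at 0.82, Sgk1 at 0.75, Cirbp at -0.89 and Opalin at -0.78. Hspa1b was at 0.66 there and not called (adjusted p 0.255). Of the deprived 12 h arrays of this series, replicates 2 and 5 had high cortical markers (mean log2 8.25 and 8.008). Replicates 3 and 4 had 7.323 and 7.356, and its sleeping 12 h arrays at most 7.291. What this adds to the Homer1 value was not tested within the series. The series of 5 had 3 deprived arrays against a single sleeping one, all at 9 h. The series of 10 and 6 had 2 deprived arrays each, against 6 and 4 sleeping, at 3 and 6 h. Their values are therefore only descriptive. In these 3 series Homer1 changed by 0.95, 0.81 and 0.90, Cirbp by -0.80, -0.70 and -0.16, Opalin by -1.12, -0.65 and -0.51, and Hspa1b by 0.57, 2.37 and 1.87. With so few arrays limma called 0, 9 and 0 probe sets in them, and 2343, 1313 and 1722 had an unadjusted p below 0.05.

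**Figure D1:**
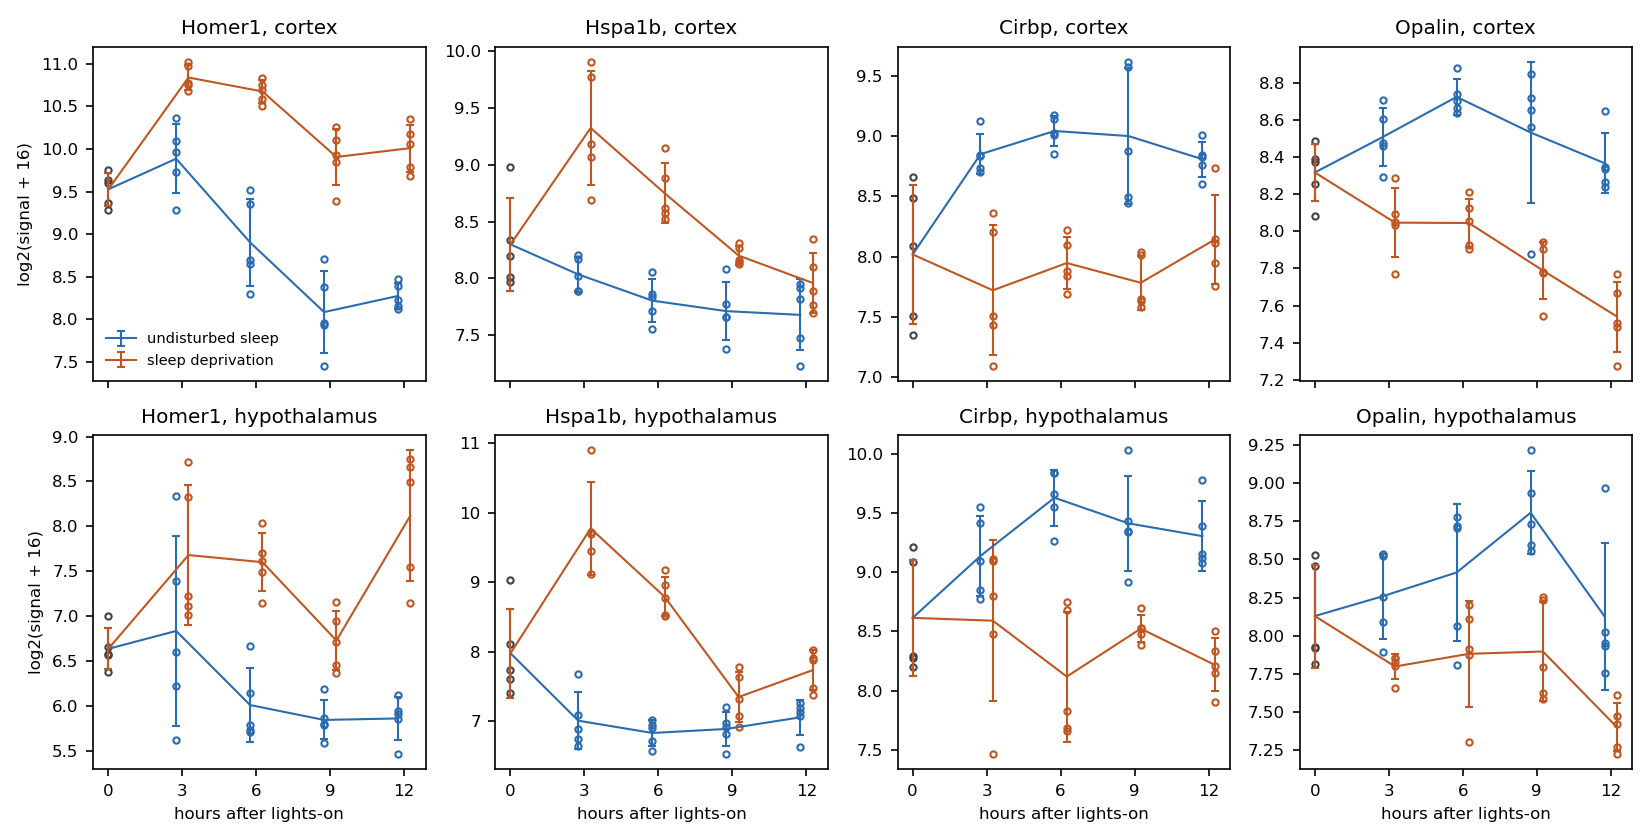
Log2 of signal plus 16 for Homer1, Hspa1b, Cirbp and Opalin (panels from left to right, cortex above hypothalamus) against hours from lights-on, with circles for single arrays and lines for group means ± SD of 5 sleeping or 5 deprived mice. Homer1 signals in cortex were 1830 and 961 after 3 h of deprivation and of sleep and 1030 and 295 after 12 h.

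Several hypothalamic lists moved in the same direction as in cortex; list results were not tested for a difference between the tissues. Of 20 heat shock genes 13 rose (15 over the list alone), with Hspa1a at 0.61 and Chordc1 at 0.71, a median of 0.29 and a camera adjusted p of 9.63e-19. Of 18 glucocorticoid-induced genes 11 rose (13 over the list alone), with Sgk1 at 0.81, Cdkn1a at 0.54 and Angptl4 at 0.51 and a median of 0.30. Of 21 immediate early genes 9 rose (12 over the list alone), with Nr4a1 at 0.50, Dusp6 at 0.47 and Egr1 at 0.42 and a median of 0.24. Of 22 endoplasmic reticulum chaperone genes 9 rose (13 over the list alone), with Hspa5 and Sdf2l1 both at 0.55 and Creld2 at 0.52, and the median was 0.22. Of 19 cholesterol genes 4 fell (10 over the list alone), with Mvd at -0.42, Fdps at -0.30, Fdft1 at -0.29 and Sqle at -0.23, and the median was -0.15. With the estimated correlation these 5 passed at adjusted p of 0.000757, 9.81e-06, 0.00111, 0.000757 and 0.00583, and their blocked medians were 0.30, 0.22, 0.24, 0.21 and -0.15. The cholesterol median within the series of 22, compared at 9 and 12 h, was -0.233.

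The medians of the energy and ribosome lists of the hypothalamus changed sign when blocked. The Gapdh 3' to 5' ratio also differs between the labelling series, and RNA quality was not tested for these lists. Respiratory chain genes were higher in deprived mice (5 of 72 rose, 12 over the list alone, median 0.17), as were mitochondrial ribosomal genes (4 of 73 rose, 10 over the list alone, median 0.0619), but the blocked medians were -0.0163 and -0.0262. Cytosolic ribosomal genes had a median of 0.11 with no gene called, and blocked they went the other way, at -0.0655. None of the 3 passed with the estimated correlation (adjusted p 0.422, 0.485 and 0.529). Meninges genes (0 of 8 called, 2 higher over the list alone, median 0.17) and interneuron genes (1 of 11 rose, 5 over the list alone, median 0.12) passed only with the preset correlation (estimated adjusted p 0.423 and 0.361), and blocked not even then (0.243 and 0.496). The clock list was not called, with 4 of 20 genes lower, among them Dbp, Per3 at -0.33 and Tef at -0.17 (lost when blocked, adjusted p 0.215). A signal for 18S ribosomal RNA was also higher in deprived hypothalamus, by 1.67 on the log2 scale (permutation adjusted p 0.00495), and its level also differed between the labelling series.

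**Figure D2:**
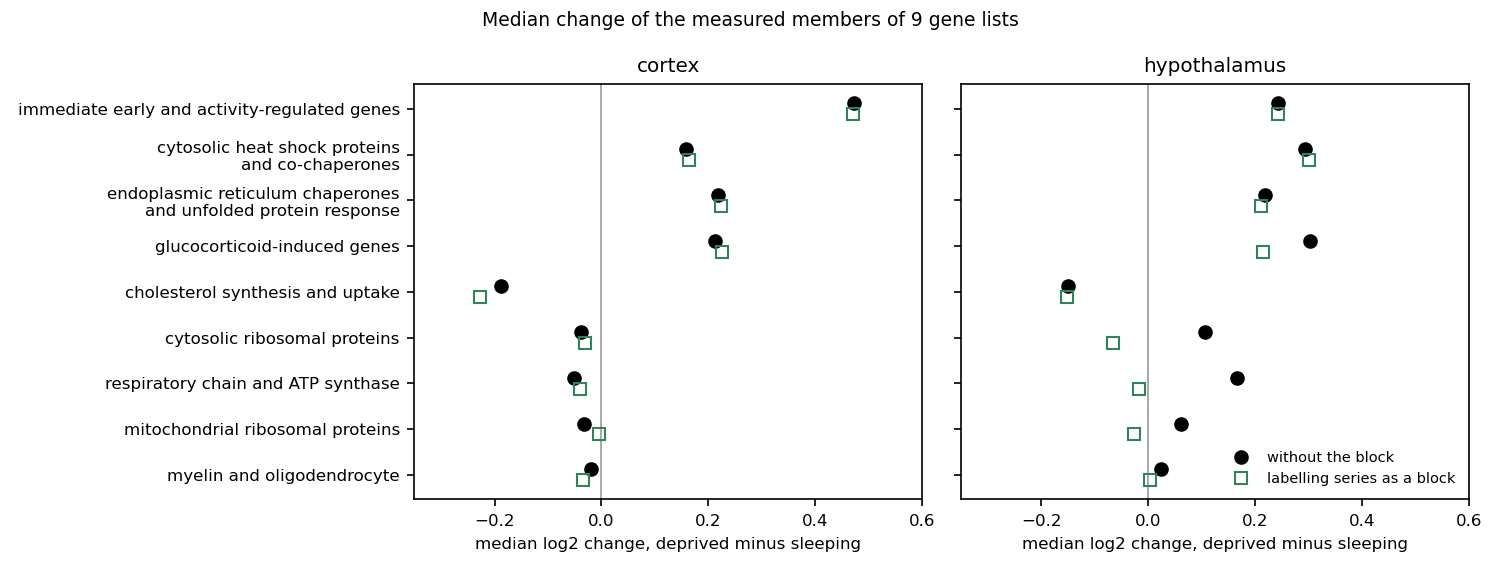
Median log2 difference between deprived and sleeping mice (mean of the 4 times, 20 arrays a side) for 9 gene lists in each tissue, without and with the labelling series as a block; no error bars are drawn. The hypothalamic respiratory chain median went from 0.17 to -0.0163, while the heat shock median stayed at 0.29 and 0.30.

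The single times of the hypothalamus (5 arrays against 5) differed widely in count. At 3 h 40 probe sets were called (28 higher, 12 lower; 28 blocked, 19 in both): Hspa1b rose by 2.77 ± 0.245 or 6.8-fold (adjusted p 3.66e-10; blocked 2.52), Hspb1 by 1.82 and Hspa1a by 1.44. Zbtb22, Rictor and Zfp810 fell by 0.71, 0.71 and 0.65, and of these only Zfp810 was kept when blocked (adjusted p 0.0159). Blocked, Zbtb22 and Rictor were at -0.53 and -0.44 (adjusted p 0.0576 and 0.302). At 6 h 4088 were called (1789 higher, 2299 lower), but 183 when blocked (119 higher, 64 lower) with 169 in both. The 6 h rises of Hsd3b3 at 2.19 and Hspa1b at 1.96 were kept at 1.51 and 1.62. Kap at 2.70 and Fscn1, Csnk1d and Kcnip3 at -1.88, -1.85 and -1.83 lost the call (blocked adjusted p 0.574, 0.174, 0.144 and 0.136). Blocked, Kap shrank to 1.08, but the falls of Fscn1, Csnk1d and Kcnip3 kept most of their size, at -1.44, -1.53 and -1.48. At 9 h 34 were called (19 higher, 15 lower; 112 blocked, 27 in both). Plin4 rose there by 1.34 and Sgk1 by 1.20, and Sin3b and Opalin fell by 0.94 and 0.91, all kept when blocked. Crybb1 at 1.11 and Tank at -0.75 lost the call, at 0.94 and -0.52 blocked (adjusted p 0.0902 and 0.108). At 12 h 34 were called (21 higher, 13 lower; 114 blocked, all 34 in both), with Homer1 at 2.26, Egr3 at 2.16 and the synaptic exchange factor gene Kalrn at 1.36 above, and Cirbp at -1.09, Flywch2 at -0.81 and Sfrp5 at -0.79 below. The 12 h deprived arrays with the highest cortical markers, replicates 1, 2 and 5 (mean log2 8.353, 8.25 and 8.008 against 7.323 and 7.356 in the others), also had the highest Homer1 (8.49, 8.75 and 8.66 against 7.14 and 7.55). Excitatory neuron markers at 12 h were higher in deprived hypothalamus by 0.53 (exact permutation p 0.0397, adjusted 0.286). With 4 marker scores as covariates Homer1 at 12 h was 1.35 (adjusted p 0.00169), and Cirbp also kept its call. Egr3 at 0.80, Kalrn at 0.49, Flywch2 at -0.64 and Sfrp5 at -0.61 lost the call (0.179, 0.394, 0.255 and 0.293). Other probe sets had the opposite sign for Sin3b (2 of 4), Rictor (1 of 2), Fscn1 (1 of 3), Csnk1d (1 of 4) and Kalrn (1 of 4). Calls at single times could rest on 1 array: without single arrays of the 10 compared, Cirbp at 12 h lost its call in 9 fits, Egr3 at 12 h in 7 and Opalin at 9 h in 9.

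**Figure D3:**
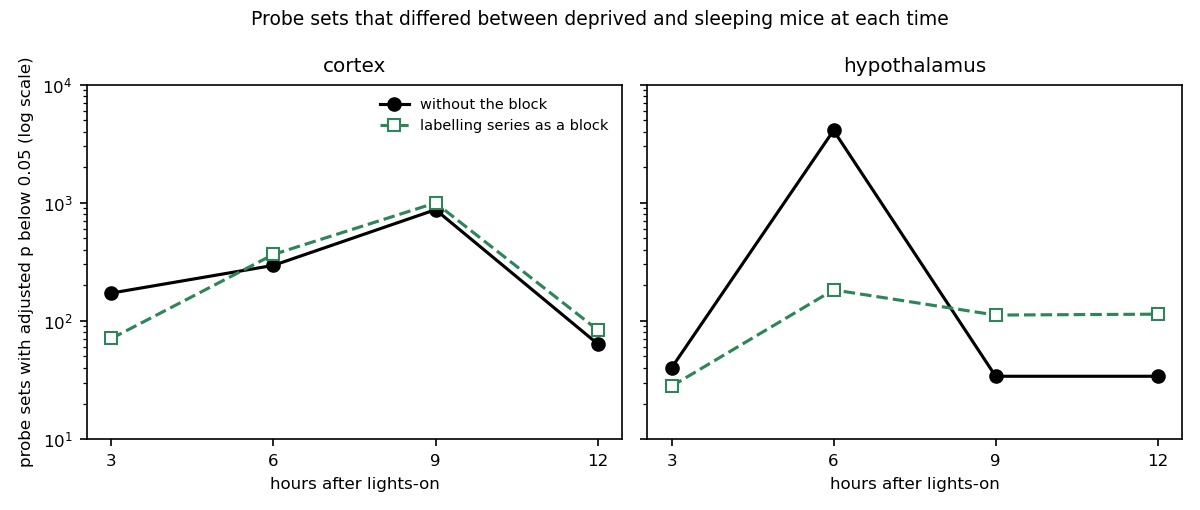
Number of probe sets called between deprived and sleeping mice at 3, 6, 9 and 12 h (log axis, 5 arrays a group) in each tissue, without and with the labelling series as a block; counts have no error bars. The hypothalamic count at 6 h was 4088 without the block and 183 with it, against 295 and 365 in cortex.

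Over the hours of sleep 82 hypothalamic probe sets had a slope (58 up, 24 down; 80 blocked, 39 in both), and over the hours of deprivation 178 (109 up, 69 down; 533 blocked, 121 in both; 25 arrays a trend). In sleep the kinase gene Sgk1 rose by 0.181 ± 0.0149 per hour (adjusted p 7.26e-11), from a signal of 377 at time 0 to 1940 at 12 h, and Zbtb16, Dbp, Ciart and Etnppl rose by 0.121, 0.109, 0.109 and 0.107. Ankrd10, Mmp14, AA388235, Itga10 and Trim9 declined by -0.0786, -0.0708, -0.055, -0.0502 and -0.0465 per hour, and of these only AA388235 was kept when blocked. The only other AA388235 probe set had the opposite sign, as had 1 of 2 for Ankrd10. In deprivation Sgk1 rose by 0.204 (adjusted p 1.4e-12), Plin4 by 0.138, Gm19439 by 0.123, Zbtb16 by 0.122 and Klf9 by 0.103, while another Hspa1b probe set, Gm266, Mmp14, Hspa1a and Wnt7a fell, at -0.112, -0.112, -0.0812, -0.0746 and -0.0652. The only other Wnt7a probe set had the opposite sign. Glucocorticoid-induced genes rose in both trends (8 of 18 in sleep, 15 up and 1 down over the list alone, estimated adjusted p 3.26e-08; 13 of 18 in deprivation, 16 over the list alone, 4.1e-10). The clock list rose too, with 4 up and 1 down of 20 in sleep (estimated adjusted p 1.72e-07, Per2 at 0.0567 per hour) and 6 up and 1 down in deprivation (9.96e-05, Arntl at -0.0418). In deprivation potassium channel genes moved up (2 of 24 rose, Kcnk1 and Kcnn2, the latter lost when blocked at 0.121; median 0.0174, estimated adjusted p 0.000359) and cholesterol genes down (none of 19 called, 3 lower over the list alone, median -0.0129, estimated adjusted p 0.0357; blocked 0.159). In sleep heat shock genes had a median of -0.0181 and immediate early genes of -0.0233 per hour, called only with the preset correlation (estimated adjusted p 0.136 for both; blocked 0.0297 and 0.157).

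The gap between deprived and sleeping hypothalamus changed with the hours for 7 probe sets (2 up, 5 down; 5 in both fits), against 2991 with an unadjusted limma p below 0.05. The Hspa1b gap shrank by -0.263 ± 0.0352 per hour (a probe set other than that of the mean comparison, adjusted p 7.76e-05; blocked -0.225, adjusted p 0.00639), and at the probe set of the mean comparison its signals were 951 deprived and 118 sleeping at 3 h against 201 and 119 at 12 h. Hspa1a shrank likewise by -0.166 (blocked adjusted p 0.0203), and Camkk2, a kinase of calcium signalling, grew by 0.111 (blocked adjusted p 0.0266). Dclk1 at 0.0744 and Smim19 at -0.0808 lost the call when blocked, at 0.0719 and -0.0555 (adjusted p 0.0714 and 0.225). Of the other Dclk1 probe sets 1 of 7 had the opposite sign. Hspa1a and Hspa1b are near-identical paralogs, and their probe sets were not told apart here.

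The tissues shared much of the mean response. Of 21450 probe sets tested in both, 282 rose in cortex and hypothalamus alike out of 1529 and 540 (38.5 expected from the totals), and 253 fell in both out of 1419 and 663 (43.9 expected); blocked, the shared numbers were 184 and 152 against 19.2 and 17.1 expected. The difference between tissues was tested directly for 21450 probe sets, with 58 called (18 higher and 40 lower in hypothalamus; 20 blocked and 16 in both). Sgsm1 rose by 0.64 in cortex and stood at -0.0774 in hypothalamus (difference -0.72, adjusted p 3.62e-08; blocked 1.06e-05), Trib2 at 0.62 and -0.0303 (-0.65, adjusted p 1.89e-07), the synaptic organizer gene Cbln4 at 0.66 and 0.0728 (-0.59, adjusted p 0.00249), and the glycolytic regulator gene Pfkfb3 at 0.56 and -0.0864 (-0.65, adjusted p 0.00126; blocked 0.0281). Hspa1b, at the probe set with the shrinking gap, was the other way, at 0.61 in cortex and 1.39 in hypothalamus (difference 0.78, adjusted p 0.00249; blocked 0.0184). Rnd3 at -0.73, Ccn3 at 0.89, Mgst3 at 0.61, Ppp1r1a at 0.57 and Snx7 at 0.53 lost the call when blocked (adjusted p 0.0976, 0.16, 0.576, 0.291 and 0.0505). Their blocked differences were -0.59, 0.67, 0.19, 0.41 and 0.55, so Mgst3 shrank most and Snx7 did not shrink. The limits of all these comparisons are 5 mice a group, a bulk tissue sample of mixed cells, and handling that came together with the loss of sleep.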

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

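Several tests of this part were chosen only after the result was seen. They were those of the labelling series on Hspa1b and Opalin, of the Gapdh ratio at 6 h and of the other oligodendrocyte markers. The marker scores used as covariates were also chosen after the data were seen. The comparison of signs at 6 h rests on labelling series that were found after the values had been seen. The other tests of this part were written down before they were run.

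The 4088 probe sets called at 6 h in the hypothalamus stand far above the 40, 34 and 34 of the other times. Differences between the series of 22 and of 10 arrays, measured only in 6 and 3 arrays of time 0 and of 3 h deprivation, had the sign of the 6 h difference for 94.2% of these probe sets (correlation 0.893), and 2 of 40 regroupings of those arrays, the real one included, gave as large a share. With the Gapdh 3' to 5' ratio as a covariate, which itself differs between the series, 143 were called, while 4 marker scores for dissection left 5444. Tissue that these 4 scores track (choroid plexus, striatum, thalamus and cortex) therefore does not account for the count. Other tissue was not scored in this fit, so dissection as such is not excluded. The labelling series and RNA quality each remain open as a likely source of most of the 6 h calls. Blocked, 183 were called, among them Hspa1b at 1.62, whose blocked difference was larger at 3 h (2.52), and Hsd3b3 at 1.51.

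The Hspa1b gap in the hypothalamus shrank with the hours, at -0.263 per hour. It was -0.225 with the series as a block and -0.222 ± 0.0394 with the 4 marker scores, and the highest adjusted p without any 1 array was 0.000306. Labelling series, the tissue that these 4 scores track and a single array are thus excluded as the whole cause. A possible reading is that handling was an unfamiliar stress at the start and less so later, and another that the clock hour limits the response; neither was tested. Blood or brain temperature and corticosterone by hour would be the next measurement.

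Opalin was lower in deprived mice of both tissues. The other 16 oligodendrocyte markers changed by -0.0597 ± 0.039 in cortex and 0.0093 ± 0.0494 in hypothalamus. Less white matter in the deprived samples is thus excluded as the main cause of the mean fall. In cortex 3 of the 16 fell and 0 rose (1 and 1 in hypothalamus). At 12 h the cortical marker list, Opalin included, was lower by 0.196 (exact permutation p 0.00794, adjusted 0.119). A contribution of less white matter in cortex is therefore not excluded. With the series as a block the differences were -0.65 and -0.69, which excludes the labelling series. The fall could be a response of oligodendrocytes themselves to wakefulness, and counting cells or staining Opalin transcript would test that.

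In 100 divisions of the same arrays the real one, itself included, was matched or passed in 1 for the cortical mean comparison (3051, next highest 11). The number was 1 at 3 h (172, 129), 1 at 6 h (295, 43), 2 at 9 h (873, 875) and 1 at 12 h (64, 6). It was 1 for the sleep trend (1470, 26) and 1 for the deprivation trend (2256, 116). A random grouping is thus an unlikely source of these counts, though at 9 h another division gave more. The divisions ignored the labelling series. At 3 h and in the trends the series run partly together with state or hours, and the divisions cannot tell these apart. For cortical growth the number was 1 as well (1, 0). A count of 1 that falls to 0 when blocked is too small to exclude chance. The 875 at 9 h came from exchanging deprived array 4 with sleeping array 4, the array with the lower quartile of 27.4 given further on. In hypothalamus the numbers were 2 for the mean (1250, 1415), 2 at 6 h (4088, 6861), 1 at 12 h (34, 2), 1 for the sleep trend (82, 5), 2 for the deprivation trend (178, 740) and 3 for growth (7, 83), and 1 for the tissue difference (58, 45). At 3 h 6 divisions reached 40 or more (up to 2090) and at 9 h 6 reached 34 or more (up to 3251), so chance cannot be excluded for those 2 counts, although single genes such as Hspa1b at 3 h have adjusted p as low as 3.66e-10. Divisions that call several times the real count point to a structure of the samples: in the hypothalamus the highest ones at 6 and 9 h separated labelling series, and that at 3 h set all arrays of the series of 22 apart from all of the series of 6, with the series of 10 on both sides. Blocked, the counts at 3, 6 and 9 h were 28, 183 and 112. For the hypothalamic mean, deprivation trend and growth, where 1415, 740 and 83 passed the real count, the blocked counts were 578, 533 and 5.

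Single arrays stood apart from their group by the Dixon test in 10 of 162 sets of 5 tested, where chance alone gives about 1 in 20, or 8.1. The lower quartile of signal was 27.4 in cortex, sleep 9 h, replicate 4 (others 18.2 to 19) and 22.2 in hypothalamus, deprived 12 h, replicate 1. The Gapdh 3' to 5' ratio (log2) was 0.987 in cortex, deprived 6 h, replicate 3, 0.0553 in cortex, deprived 9 h, replicate 1, and 0.0837 in hypothalamus, sleep 6 h, replicate 5. Hspa1b had a log2 signal of 6.63 in hypothalamus, sleep 12 h, replicate 1, the array that also had Opalin at 8.97. Opalin was 8.65 in cortex, sleep 12 h, replicate 3, where Dbp was 9.72, and 7.66 in hypothalamus, deprived 3 h, replicate 1. Of these arrays, the hypothalamic ones of deprived 12 h replicate 1, sleep 6 h replicate 5 and sleep 12 h replicate 1 were each the only array of their labelling series in their group. The poly-A control probe sets at 9.94 in 6 hypothalamic arrays are not explained by the labels.

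The genes of this paragraph are here because a test of the difference between times or tissues called them. Of the genes whose gap changed with the hours, Irak1 in cortex changed by -0.145 per hour and, in hypothalamus, Camkk2 by 0.111, Dclk1 by 0.0744, Hspa1a by -0.166 and Smim19 by -0.0808. Of the genes that differed between tissues, the hypothalamic minus cortical effect was -0.65 for Pfkfb3, -0.73 for Rnd3, 0.57 for Ppp1r1a, -0.65 for Trib2, 0.89 for Ccn3, 0.78 for Hspa1b, 0.53 for Snx7, -0.59 for Cbln4, -0.72 for Sgsm1 and 0.61 for Mgst3.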

How the results depend on the processing

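The labelling series block, the Gapdh ratio, the 4 marker scores and the omission of 2 cortex arrays were chosen only after the results were seen; the other settings were listed in advance.

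With the labelling series as a block, cortex had 71 calls at 3 h, 887 for the sleep trend and 0 for growth (1772 with an unadjusted limma p below 0.05), and the sleep slope of Anp32a turned to 0.0113. The hypothalamus had 578 for the mean, 183 at 6 h, 112 at 9 h, 114 at 12 h and 533 for the deprivation trend, and the tissue difference had 20. Of 423 gene calls 304 were kept, 118 were lost and 1 reversed. A block for early against late hours left 0 calls for the cortical sleep trend and 35 for deprivation, and 11 and 8 in hypothalamus.

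With the Gapdh 3' to 5' ratio as a covariate, cortex had 99 calls at 12 h and 2 for growth; hypothalamus had 91, 143, 99 and 85 at 3, 6, 9 and 12 h, 150 and 301 for the sleep and deprivation trends and 14 for growth. With 4 marker scores, the hypothalamic counts were 2340 for the mean, 26 at 3 h, 5 at 12 h and 2 for growth. Without the 2 doubted cortex arrays the cortical counts were 365 at 3 h, 1447 at 9 h, 155 at 12 h and 2 for growth. Fits of only the 2 groups compared gave 75, 65, 29 and 41 in cortex and 10, 1189, 4 and 8 in hypothalamus at 3, 6, 9 and 12 h.

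Without a filter the counts were 114 at 3 h in cortex, 20 at 12 h in hypothalamus and 32 for the tissue difference, and 11 lists passed for the cortical deprivation trend and 17 for the hypothalamic sleep trend. The stricter filter gave 1445 for the cortical deprivation trend, 0 for cortical growth and 4 lists for that deprivation trend. Quantile normalization gave 13 for hypothalamic growth and kept 405 of 423 gene calls, and log2(value + 1) moved no count by more than 1.5-fold. With the estimated correlation the lists called were 5, 4 and 2 in cortex (mean, sleep trend, deprivation trend) and 5, 2 and 4 in hypothalamus, in place of 11, 13, 7, 10, 10 and 10. Blocked, with the preset correlation, they were 9, 11 and 7 in cortex and 8, 12 and 13 in hypothalamus. The block for early against late hours takes away most of a trend by its construction; the cause of the other shifts was not tested.

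The replicate number as a block gave 2992 for the mean in cortex and 1438 in hypothalamus. Residuals of arrays with the same number correlated above 0.1 in 2 of 20 cortical pairs (median -0.0174, highest 0.12) and in 11 of 20 hypothalamic pairs (median 0.159, highest 0.457), and the own number was the best match in 3 and 7. The numbers were not taken as pairs, since not every pair passed 0.1; part of the hypothalamic arrays of the same number were more alike than the rest, and the cause was not tested.

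Leaving out each array in turn gave these lowest and highest counts in cortex, with every array named that moved a count over 1.5-fold (group, hours and replicate number). The mean had 2642 to 3688. At 3 h it was 62 (without deprived replicate 3) to 236, with 94, 107 and 88 without sleep 1, 2 and 5 and 102 and 106 without deprived 1 and 2. At 6 h it was 179 (without deprived 3) to 336, with 191 and 193 without sleep 1 and 4. At 9 h it was 351 (without sleep 3) to 1220, with 548 without sleep 2 and 509, 392 and 486 without deprived 1, 3 and 5. At 12 h it was 30 (without sleep 4) to 79, with 31 without sleep 5 and 33 and 42 without deprived 3 and 4. The sleep trend had 927 (without sleep 12 h 1) to 1628, with 941 without time 0 replicate 5 and 971 without sleep 12 h 3, and the deprivation trend 1744 to 2596. Growth had 0 (without deprived 3 h 3 or sleep 12 h 4) to 3 (without sleep 3 h 3 or deprived 3 h 1), and 2 without deprived 3 h 2, deprived 6 h 3 or deprived 12 h 2.

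In hypothalamus the mean had 865 to 2171 (without deprived 6 h 4), with 1910 without deprived 3 h 4. At 3 h it was 22 (without sleep 5) to 128 (without deprived 4), with 23 and 123 without deprived 3 and 5. At 6 h it was 836 (without deprived 2) to 6726 (without deprived 4), with 2203 and 1401 without deprived 1 and 3 and 2293 and 1829 without sleep 2 and 4. At 9 h it was 4 (without sleep 3) to 86 (without sleep 2), with 9 and 17 without sleep 4 and 5 and 9, 11 and 15 without deprived 1, 2 and 3. At 12 h it was 5 (without deprived 1 or 5) to 72 (without deprived 3 or 4), with 9 without deprived 2 and 8, 10, 6 and 13 without sleep 2, 3, 4 and 5. The sleep trend had 59 to 85 and the deprivation trend 100 (without deprived 12 h 5) to 230, with 111 and 117 without time 0 replicates 2 and 5. Growth had 5 to 21 (without deprived 12 h 4), with 20 without sleep 3 h 1 or deprived 3 h 4, 13 without deprived 3 h 1 or deprived 12 h 3, 11 without deprived 6 h 5 and 12 without deprived 9 h 4. The tissue difference had 32 (without hypothalamus deprived 12 h 5) to 119 (without hypothalamus deprived 6 h 4), with 91 and 94 without hypothalamus deprived 3 h 4 and 6 h 5, 37 and 38 without hypothalamus sleep 12 h 3 and 4, and 35, 36 and 37 without cortex deprived 3 h 3, sleep 6 h 3 and deprived 6 h 3. Of 423 gene calls 305 held without every array and 118 were lost without at least 1.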

Other observations

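The comparison of Cirbp with the heat shock list was written down in advance, but its comparison with random lists was chosen only after the correlation was seen.

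Several gene groups not described above held single genes that changed. Of the GABA genes in cortex 2 of 14 rose and 2 fell, Gabra2 at 0.43 and Gabrd at -0.31 among them, and Gabra2 also rose in hypothalamus, at 0.53. The connexin gene Gjb6 of astrocytes rose in both tissues, at 0.40 and 0.33, in a list where 2 of 14 rose and 2 fell in cortex and 2 of 14 rose in hypothalamus. In hypothalamus the potassium channel genes Kcnk1 and Kcnn2 rose in the mean comparison too, at 0.28 and 0.27. Of the glutamate receptor and scaffold genes 3 of 19 rose in hypothalamus and 1 of 20 in cortex, but blocked it was 0 and 3. Of 34 translation factors 1 rose and 5 fell in cortex and 2 fell in hypothalamus; of 73 mitochondrial ribosomal genes 10 fell in cortex, led by Mrpl16 at -0.28. The secretory granule gene Scg2, of the pituitary list, rose in cortex, at 0.40, and was not called in hypothalamus, while Chga was called in neither; of the red blood cell list Bpgm fell in cortex, at -0.20, and Hbb-b2 was not called. The lists of this paragraph were not tested for a difference between tissues.

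Lists with few or no calls in the cortical mean comparison were cytosolic ribosomal genes (2 of 43 fell), glycolysis (2 of 21 fell), haem synthesis (1 of 7 fell), vesicle trafficking (1 of 42 fell), potassium channels (2 of 25 rose and 2 fell), microglia (3 of 12 fell), endothelial cells (2 of 12 rose), meninges (1 of 9 rose), excitatory neurons (1 of 13 rose), interneurons (2 of 12 rose), and, with none called, choroid plexus (8 genes), striatum (12), thalamus (10) and hypothalamic transcription factors (7). In hypothalamus 3 of 22 neuropeptide genes rose, 2 of 18 cold-inducible and splicing genes rose and 2 fell, 1 of 17 myelin genes rose and 2 fell, and none of 12 hypothalamic transcription factors was called. Blocked, no microglia or meninges gene was called in cortex, and 3 genes fell in each of the glycolysis and vesicle trafficking lists. Blocked in hypothalamus, 1 neuropeptide gene, 1 cold-inducible or splicing gene, 1 astrocyte gene and no myelin gene rose, while the translation factor and hypothalamic transcription factor lists were called lower with the preset correlation (adjusted p 0.000337 and 0.0248) but not with the estimated one (0.091 and 0.57).

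Over the hours of cortical sleep, ribosomal, mitochondrial ribosomal, respiratory chain, glycolysis, haem and excitatory neuron lists went up and the endothelial list went down, but with the estimated correlation their adjusted p were 0.501, 0.372, 0.488, 0.476, 0.0732, 0.179 and 0.181, and blocked the last 4 were not called with the preset correlation either. Over the hours of cortical deprivation the cholesterol, choroid and thalamus lists went down, with 0.411, 0.515 and 0.571, and blocked the cholesterol and thalamus lists were not called with the preset correlation either (0.0563 for both). In sleeping hypothalamus ribosomal, mitochondrial ribosomal, respiratory chain, choroid and thalamus lists went up and the striatum list down, with 0.412, 0.351, 0.348, 0.136, 0.348 and 0.399. Blocked, the direction turned for the ribosomal list (median -0.016 per hour, preset adjusted p 3.6e-07), the respiratory chain (-0.0117, 8.38e-05) and the mitochondrial ribosomal list (-0.00603, 0.131), and the choroid list was not called (0.196). In deprived hypothalamus immediate early, glutamate, choroid and excitatory neuron lists went up and heat shock and hypothalamic transcription factor lists down, with 0.226 for the first and 0.115 for each of the others; blocked, the immediate early, choroid and excitatory neuron lists were not called (preset adjusted p 0.0554, 0.134 and 0.136). The choroid, striatum, thalamus and excitatory neuron markers vary with where the tissue was divided.

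Cirbp and the heat shock genes moved in opposite directions between states, and they did so between single mice as well. Within groups and labelling series, residuals of Cirbp and of the heat shock list mean correlated at r -0.422 in cortex (permutation p 0.00381, adjusted over the 2 tissues 0.00381, with rho -0.48, permutation p 0.00097). In hypothalamus r was -0.546 (permutation p 0.00036, adjusted 0.00072, with rho -0.471, permutation p 0.00135). These p-values are 2-sided and over 45 arrays each. The shuffling took the 45 residuals as free, although the fitted groups and series tie them, so these p-values are too small. Without the 2 arrays farthest out r was -0.474 and -0.373, and within series of 6 or more arrays it was -0.433 and -0.423 in cortex and -0.506, -0.652 and -0.652 in hypothalamus. The values within series are parts of the same residuals and no independent test. In the hypothalamic series of 6 only the group of 3 h sleep had more than 1 array. Random lists of the same size gave as low a value in 1.22% and 0.14% of 10000 draws, although genes of the heat shock list vary together more than random genes do. Both could follow the temperature of the single animal, since Cirbp is induced by cooling and heat shock genes by warming; a telemetric record of brain temperature in each mouse would test this, and RNA quality of single arrays remains open as another source.

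Title numbers of cortex and hypothalamus arrays differ by 79 in 39 pairs of the same condition. If both arrays of a pair came from 1 mouse, residuals should correlate, and the mean correlation was 0.026 against a mean of -0.00154 (SD 0.0167) for 10000 re-pairings, with 95.3% of re-pairings below it (1-sided permutation p 0.0473). In the real pairing 14 probe sets had a correlation over 0.6, against at most 11 in 100 re-pairings. Hspa1b had the highest correlation of all probe sets, at 0.743, and Fos had 0.612, both chosen after their values were seen; 2 of the 100 re-pairings reached a value as high as that of Hspa1b, up to 0.753. The pairs may be mice: the mean correlation and the number of high correlations lie just above the re-pairings, but the consensus correlation in limma was only 0.00217, and no result above uses the pairing.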
